A study of Mus musculus with 6 samples.

How the data were processed

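RNA was sequenced from MLO-Y4 cells, a mouse line with features of osteocytes, the cells embedded in bone. The 6 libraries were assigned by their labels to 20% O2 (3 libraries, normoxia, replicates 2, 3 and 4) or 2% O2 in a hypoxic chamber (3 libraries, hypoxia, replicates 1, 2 and 4), both for 24 h. The descriptions of some libraries state 25 or 26 h where their titles state 24 h. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, the RNA was treated with DNase, only samples with an RNA integrity number of at least 8 were used, and libraries were made with a stranded kit for messenger RNA. The submitters' processing notes name FastQC 0.12.0, DRAGEN, and the mouse genome build GRCm39 (mm39). The version of DRAGEN and its settings are not given in the sources used here.

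The table analysed here lists 2065 genes with a log2 entry per library, which the authors deposited. Raising 2 to each entry and subtracting 1 gave a number with 3 decimals for 100% of entries (tolerance 1e-06), so the entries were read as log2(value + 1). Per the file headers the linear unit has no name, and sequencing depth is unknown. The log2 fold change the authors deposited equals the mean of the hypoxia entries minus the mean of the normoxia entries. Every listed gene has an absolute log2 fold change of at least 1.00 and an adjusted p-value, as deposited by the authors, of at most 0.0926. The test behind that p-value is not given in the sources used here. The table therefore holds genes that the authors selected for change in these same libraries, and genes outside it were not analysed here. For this reason no count below is independent evidence of a change, whichever way its p-values were adjusted, and shares of higher and lower genes refer to the selected genes. Further sheets repeat the 15 genes with the largest rise and the 15 with the largest fall, and give the authors' fold change and adjusted p for 4 genes, of which Tgfb1 is outside the larger table. Another 21 columns were not used: 18 repeat values per library for selected genes, and 3 hold values for mice that belong to no sample of the series.

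The design fixed before the data were examined named a count model, and gave a test for normalized values if counts were not found. The entries are not counts, so that second test was used: limma 3.58.1 in R 4.3.3, with a trend in the variance and robust estimation, on log2(value + 1), the pseudocount being 1. Genes with a value of at least 1 in at least 3 libraries were tested (2056 genes, 9 left out). P-values are two-sided, adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Differences are the mean of the libraries labelled hypoxia minus that of the libraries labelled normoxia, so a positive value is higher under the hypoxia label. A difference of 1 on this scale is a 2-fold difference for well expressed genes and understates the ratio of genes with low values. On simulated values for the same 2056 genes, the test called 98% of genes changed by 1 and 74% of genes changed by 0.5 on the log2 scale, and 6 of 1856 unchanged genes. The simulation changed 200 genes and used the spread of the selected genes, where in the table every gene had been selected for change. These rates therefore describe the test in that setting only.

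Of 38 gene lists fixed before the data were examined, the 23 with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Camera compares a list with the other tested genes, which were selected for change and are 79.4% higher. A further list of HIF target genes was written after the first list had been seen, and a two-sided Fisher's exact test of directions was added then too. Genes named by rule were the 10 largest changes in each direction among genes with adjusted p under 0.05, a mean value of at least 5 and no overlap between groups, up to 4 members of each list with the smallest adjusted p, 19 genes chosen in advance, and the genes of the short sheets. Predicted genes were counted and not named, and values of some single genes are not reported here. Genes named beyond this rule were chosen after their values were seen. Of the 19 genes chosen in advance, Epas1, Car9, Pdk1, Egln3, Sost, Dmp1, Phex, Gja1, Tnfrsf11b and Fgf23 are outside the selected genes and have no value here.

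Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5, quantile normalization, trimmed mean (TMM) factors, limma without trend, a replicate block, leaving out each library, and a threshold of 0.01. Transcript lengths and GC content came from GENCODE vM21 transcripts matched by Ensembl gene identifier (98.1% of listed genes). That annotation is of an older build than the authors used, so no coordinates were taken from it. Listed processed pseudogenes were aligned to its protein-coding transcripts of other genes with BLAST+ 2.17.0, keeping matches of at least 90% identity over at least 50% of the pseudogene. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.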

Results

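The transcriptome of MLO-Y4 cells was measured by messenger RNA sequencing in 3 libraries labelled normoxia (20% O2) and 3 labelled hypoxia (2% O2), after 24 h. The table analysed holds 2065 genes that the authors selected for change between these groups, as log2(value + 1) with no named linear unit, so depth per library is unknown. The summed linear values of the listed genes were 175405, 176070 and 183535 in the libraries labelled normoxia and 166071, 161067 and 161817 in those labelled hypoxia. Libraries of the same label correlated across the tested genes with r from 0.991 to 0.995, and libraries of different labels with r from 0.762 to 0.805, on genes chosen for that difference. All values below are means on the log2(value + 1) scale with the SD of 3 libraries, and each change is given with its standard error.

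The comparison asks which genes respond to low oxygen in osteocyte-like cells. Targets of hypoxia-inducible factor (HIF), the transcription factor that accumulates when oxygen is low, were lower in the libraries labelled hypoxia. Of 32 HIF target genes on the list fixed in advance, 19 were among the selected genes, and 18 of them were lower and 1 was higher. The glucose transporter Slc2a1 (ENSMUSG00000028645, chromosome 4) went from 10.85 ± 0.10 (SD, n = 3) in the libraries labelled normoxia to 7.72 ± 0.12 (SD, n = 3) in those labelled hypoxia, a change of -3.13 ± 0.09. The oxidase of the endoplasmic reticulum Ero1a (ENSMUSG00000021831, chromosome 14) went from 12.23 ± 0.09 to 9.13 ± 0.22, and the prolyl hydroxylase Egln1, which marks HIF for degradation, from 7.38 ± 0.02 to 5.77 ± 0.23. Because this group goes against the labels, every direction below is given by label only, as "the libraries labelled hypoxia" or "labelled normoxia".

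Among the other HIF targets, Bhlhe40 changed by -3.40 ± 0.09, Bnip3 by -2.02 ± 0.10, Ndrg1 by -1.96 ± 0.09 and the vascular growth factor Vegfa by -1.03 ± 0.07. The higher member was Pfkfb4, at 3.38 ± 0.44 under the normoxia label and 4.84 ± 0.08 under the hypoxia label. All 19 passed limma's test, and the same 18 lower and 1 higher passed adjusted over the list alone. Camera called the list lower (Benjamini-Hochberg adjusted p = 6.56e-14), and with an estimated correlation camera gave an adjusted p = 0.261. The list's median change was -1.96. With TMM factors the call of Pfkfb4 ended (change 0.24; limma, adjusted p = 0.27). Of the regulators of HIF, Hif1a itself was higher in the libraries labelled hypoxia, from 6.16 ± 0.02 to 7.63 ± 0.03, a call that TMM factors ended (change 0.18; limma, adjusted p = 0.0532).

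**Figure D1:**
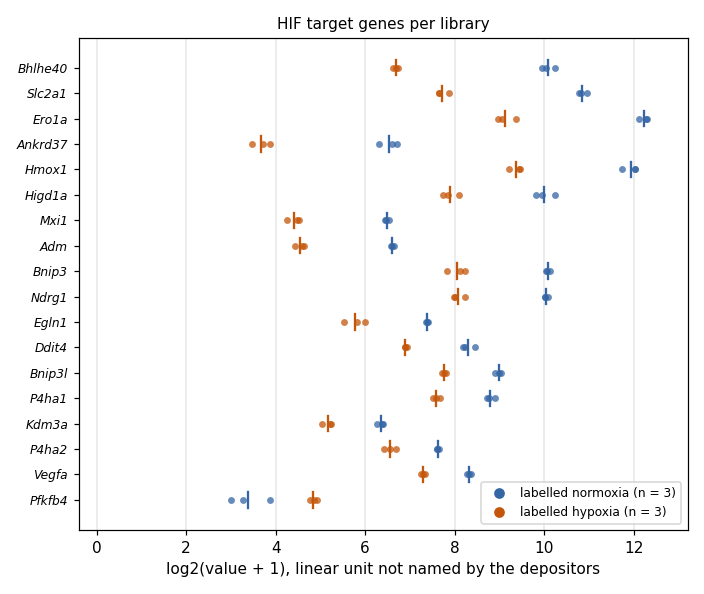
Expression of 18 of the 19 listed HIF target genes in each of the 6 libraries, on the log2(value + 1) scale (x axis); points are libraries and vertical bars are means of 3 libraries. In 17 genes the libraries labelled hypoxia lie below those labelled normoxia, and in Pfkfb4 above, which is not called with TMM factors.

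Across the table, 1633 of 2056 tested genes (79.4%) were higher and 423 lower in the libraries labelled hypoxia by limma's test. The groups of libraries overlapped in 2 of the 2065 listed genes. Chance would separate 10% of unselected genes completely, but these genes were chosen for change between the groups, so little overlap follows from the selection. TMM factors, which by construction assume that most genes in a table are unchanged, moved the median change of all tested genes from 1.15 to 0.0029, and quantile normalization moved it to 0.36. With TMM factors, 546 genes were higher and 513 lower. Of the 1633 higher genes, TMM factors left 546 called higher, 997 not called and 90 called lower, and quantile normalization left 1389 called higher. TMM lowered every change, so a lower gene could not turn under it. For the higher members of each group, those that fell below 0 and those still called higher under TMM are counted below.

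The largest rise on the log2(value + 1) scale was that of Lcn2 (ENSMUSG00000026822, chromosome 2), the iron-sequestering protein lipocalin 2, which rose from 4.58 ± 0.90 to 10.24 ± 0.06 in the libraries labelled hypoxia (change 5.66 ± 0.41; limma, Benjamini-Hochberg adjusted p = 4.2e-06). The acute-phase genes Saa3 and Hp rose by 5.35 ± 0.11 and 5.09 ± 0.09. Among chemokines, Cxcl5 rose by 4.56 ± 0.13, Cxcl2 by 4.33 ± 0.26 and Ccl2 by 4.27 ± 0.10, and the cytokine Il6 rose by 3.99 ± 0.12. The largest rises also took in Angptl4, a hypoxia-inducible inhibitor of lipoprotein lipase (from 2.63 ± 0.47 to 6.63 ± 0.10), the interleukin subunit Il12b (3.75 ± 0.13) and the fatty acid receptor Gpr84 (3.57 ± 0.11). As ratios of mean linear values, Il12b (243.6, from 0.055 under the normoxia label) and Hp (50.5) rose more than Lcn2 (45.6). Of the 26 NF-kB targets on the list, 21 were listed, 19 higher (Relb below 0 and 16 still called under TMM) and 2 lower. The 2 lower ones were Cxcl10 (change -2.65), an interferon-inducible chemokine, and Ptgs2 (-1.07), which makes prostaglandins. Camera's adjusted p for this list was 0.209 as deposited, 0.0215 with quantile normalization, 0.000129 with TMM factors and 0.707 with an estimated correlation, and its median change was 1.89 where that of all tested genes was 1.15. Of the 18 macrophage and osteoclast markers, Mmp9 (1.16 ± 0.15, from 0.13 ± 0.03 to 1.29 ± 0.33) was higher and Cd68 (-1.46 ± 0.11) was lower.

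Of 27 secreted regulators of osteoclasts, 14 were listed (9 of them also NF-kB targets), 12 higher in the libraries labelled hypoxia (10 still called under TMM) and 2 lower, beside 79.4% higher of all tested genes. Camera's adjusted p was 0.362 as deposited, 0.00282 with TMM factors and 0.806 with an estimated correlation. Tnfsf11, which encodes RANKL, the main signal for osteoclast formation, rose from 0.76 ± 0.15 to 3.24 ± 0.06 in the libraries labelled hypoxia (2.48 ± 0.11). Csf1, the growth factor of osteoclast precursors, rose from 8.38 ± 0.17 to 9.87 ± 0.04, a call that TMM factors ended (change 0.20; limma, adjusted p = 0.104). For Tgfb1, the authors' deposited table gives a log2 fold change of 0.68 and an adjusted p of 0.0060. The authors picked Tnfsf11, Csf1, Hif1a and Tgfb1 from these libraries, so they are not independent evidence of a direction.

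Interferon, heat shock and clock genes were mostly lower in the libraries labelled hypoxia. Ifnb1 (ENSMUSG00000048806, chromosome 4), which encodes interferon beta, was at 4.70, 4.96 and 5.49 in the libraries labelled normoxia, and at 0, 0.05 and 0 in those labelled hypoxia. All 11 listed interferon-stimulated genes of 32 were lower, among them Ifit3 (-4.58 ± 0.13), Ifit3b (-4.23 ± 0.14), Ifit1 (-2.64 ± 0.08) and Mx2 (-2.05 ± 0.11). Reads of Ifit3 and Ifit3b, near-identical neighbours, cannot be assigned with certainty. Camera called the list lower (Benjamini-Hochberg adjusted p = 5.43e-09; adjusted p = 0.261 with an estimated correlation).

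The small heat shock protein gene Hspb1 fell from 7.23 ± 0.25 to 2.43 ± 0.13, and its pseudogene Hsp25-ps1, which may share its reads, from 6.62 ± 0.15 to 1.98 ± 0.07. The inducible chaperone Hspa1b changed by -4.21 ± 0.10 and its co-chaperone Dnajb1 by -3.16 ± 0.11. Hspa1b and its near-identical copy Hspa1a (-2.35 ± 0.09) are uncertain as single genes. Of 7 listed heat shock genes 5 were lower and 2 were higher, the collagen chaperone Serpinh1 (1.58 ± 0.09) and Chordc1 (1.15, below 0 under TMM). For this list camera gave an adjusted p = 0.00114 (Benjamini-Hochberg), and an adjusted p = 0.261 with an estimated correlation.

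Of 8 listed clock genes, 7 were lower, among them Bhlhe40, which is also on the HIF list. The repressor Nr1d1 fell from 7.94 ± 0.15 to 3.91 ± 0.11, and the output gene Dbp and the period gene Per1 changed by -2.56 ± 0.07 and -2.39 ± 0.11. Arntl, the activator that Nr1d1 represses, was the higher one (1.43). Camera's Benjamini-Hochberg adjusted p was 5.64e-06 (adjusted p = 0.261 with an estimated correlation).

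**Figure D2:**
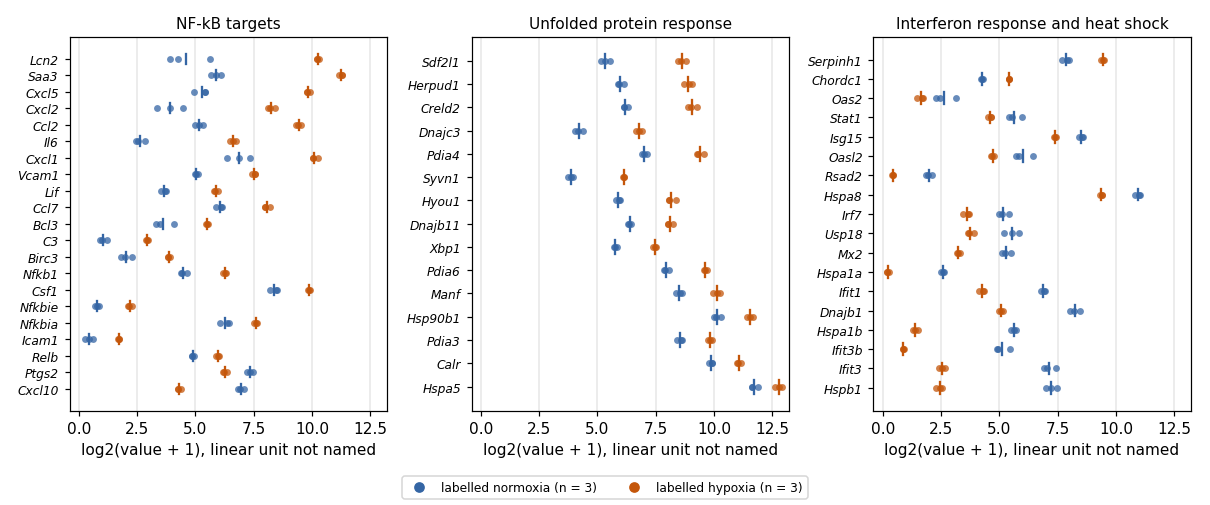
Expression per library of the listed NF-kB targets (left), unfolded protein response genes (middle), and interferon and heat shock genes (right), on the log2(value + 1) scale; points are libraries and vertical bars are means of 3 libraries. In the libraries labelled hypoxia 19 of 21, 15 of 15, and 2 of 18 genes are higher; under TMM scaling Relb, then Calr, Hspa5 and Pdia3, then Chordc1 change sign.

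All 8 listed glycolysis genes of 21 were lower in the libraries labelled hypoxia, among them Eno2 (-3.70 ± 0.12), Gpi1 (-2.16 ± 0.07) and Gapdh. Slc2a1, also on the HIF list, is counted among the 8. Gapdh, often used as a reference gene, went from 13.08 ± 0.09 to 10.89 ± 0.14. Its value is uncertain because 55 listed processed pseudogenes have Gapdh as their closest coding transcript. Camera called glycolysis lower (Benjamini-Hochberg adjusted p = 5.86e-08; adjusted p = 0.261 with an estimated correlation). In contrast, 9 of 15 mitochondrially encoded genes were listed, all higher (mt-Nd5 below 0 and 7 still called under TMM), with mt-Cytb at 6.64 ± 0.42 and 8.94 ± 0.07 and mt-Nd1 at 7.38 ± 0.24 and 9.01 ± 0.02. For them camera's adjusted p was 0.324 as deposited, 0.0306 with TMM factors and 0.806 with an estimated correlation. Of nuclear genes for respiration, Ndufa9 (1.30 ± 0.07), Ndufa4 (1.04 ± 0.07) and the citric acid cycle gene Suclg1 (1.23 ± 0.08) were listed, and the last 2 fell below 0 under TMM, which left none of the 3 called higher. Both listed mitophagy genes, Bnip3 and Bnip3l (-1.22 ± 0.07), were lower, and both are also on the HIF list.

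Of 20 genes of the unfolded protein response 15 were listed, all higher in the libraries labelled hypoxia, with Calr, Hspa5 and Pdia3 below 0 and 11 still called under TMM. Sdf2l1 rose from 5.34 ± 0.20 to 8.61 ± 0.17, Herpud1, a part of protein degradation at this membrane, by 2.92 ± 0.11, and Creld2 by 2.85 ± 0.10. Camera's adjusted p was 0.0512 as deposited, 0.0395, 0.0357 and 0.0461 without hypoxia replicate 1, 2 or 4 in turn, and 0.0916, 0.0563 and 0.0632 without normoxia replicate 2, 3 or 4. Camera also gave an adjusted p of 0.0572 with a pseudocount of 0.1 and 0.0612 with a filter of 5, of 0.0375 with a pseudocount of 5, 0.000565 with quantile normalization, 0.00103 with TMM factors and 0.707 with an estimated correlation. The 6 listed genes of the ATF4 response (2 below 0 and 1 still called under TMM), such as the amino acid transporter Slc7a5 (1.82 ± 0.07) and the serine synthesis gene Psat1 (1.51 ± 0.08), and the 8 listed genes of cholesterol synthesis (2 below 0 and 2 still called under TMM), such as Idi1 (1.46 ± 0.09) and Cyp51 (1.45 ± 0.09), were all higher. Camera's adjusted p was 0.282 and 0.238 for these lists. Lipid genes were 5 higher (2 below 0 and 3 still called under TMM), with Dgat2, an enzyme of triglyceride synthesis, at 2.13 ± 0.11, and 2 lower (camera adjusted p = 0.85). In the iron and antioxidant lists the heme-degrading enzyme Hmox1 (-2.56 ± 0.11, also on the HIF list) and the ferritin chain Ftl1 (-1.80 ± 0.09) were lower. The importers Slc39a14 (1.87 ± 0.09) and Slc11a2 (1.42 ± 0.07) and the superoxide dismutase Sod2 (1.75 ± 0.07) were higher. The medians of these 2 lists were 1.20 and 1.05, while camera pointed down for both (adjusted p = 0.493 and 0.338), and the means were 0.22 and -0.05. Under TMM 2 of the 4 higher iron genes and 1 of the 3 higher antioxidant genes fell below 0, and 1 in each list was still called higher.

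Of 30 structural matrix genes 12 were listed, 11 higher (3 below 0 and 5 still called under TMM) and 1 lower, beside 79.4% higher of all tested genes, with Col3a1 at 4.49 ± 0.72 and 7.80 ± 0.06, Col1a2 at 1.34 ± 0.12 and 3.19 ± 0.06, and Col5a2 at 4.23 ± 0.05 and 6.06 ± 0.03. The collagenase Mmp13 and the stromelysin Mmp3 rose by 2.90 ± 0.10 and 3.51 ± 0.10, and the collagen hydroxylase P4ha1, also on the HIF list, changed by -1.21 ± 0.08. Matrix modifying enzymes were 7 higher (1 below 0 and 5 still called under TMM) and 2 lower, and camera's adjusted p was 0.362 for matrix genes and 0.957 for these enzymes. Of the osteoblast genes 6 were higher (5 still called under TMM) and 2 lower (camera adjusted p = 0.868, pointing down where the median of 1.44 and mean of 0.88 are above 0). Osteocalcin gene Bglap2 rose by 1.87 ± 0.13, Spp1, which encodes osteopontin, by 1.10 ± 0.07 (below 0 under TMM), and the mineralization phosphatase Phospho1 changed by -2.24 ± 0.10. The listed osteocyte markers were Trp53inp2 (1.98 ± 0.11) and podoplanin, Pdpn (1.76 ± 0.07). The Wnt receptor gene Fzd1 rose by 1.48 ± 0.14.

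Angiogenic factors were 4 higher (3 still called under TMM) and 6 lower, with a mean change of -0.05 and a median of -1.07. Adrenomedullin, Adm, was at -2.05 ± 0.08, Ccn1 at -1.93 ± 0.08, Ccn2 at -1.73 ± 0.11 and Pdgfa at 1.85 ± 0.08. Adm and Vegfa, both lower, are also on the HIF list. Camera called the angiogenic list lower than the other tested genes (Benjamini-Hochberg adjusted p = 0.0136). Camera's adjusted p was 0.261 with an estimated correlation and 0.215 with TMM factors. Of 5 listed genes of TGF-beta and BMP signalling 2 were higher, the BMP targets Id3 (3.18 ± 0.09) and Id1 (1.89 ± 0.07), and 3 were lower, among them Id2 (-1.87 ± 0.11) and the activin subunit Inhba (-1.32 ± 0.07). Camera and the median of this list pointed down where its mean was above 0, and camera's adjusted p was 0.139. The 3 listed oxygen-dependent chromatin enzymes, Tet2 (-2.01 ± 0.10), Kdm4b (-1.22 ± 0.10) and Kdm3a (-1.18 ± 0.08, also on the HIF list), were lower.

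Of the mitosis list 0 of 30 genes were among the selected genes, of the ribosomal protein list 0 of 37 and of the replication list 3 of 35. The replication genes Tyms (1.28 ± 0.07) and Gins3 (1.08 ± 0.12) both fell below 0 under TMM. All listed members of the p53 (8 of 18, with Eda2r at 1.47 ± 0.09), apoptosis (8 of 20, with Bid at 2.15 ± 0.08) and ribosome biogenesis (5 of 28, with Tsr1 at 1.42 ± 0.09) lists were higher, and 4, 5 and 3 of them fell below 0 under TMM, where 2, 3 and 0 were still called higher. Camera's adjusted p was 0.245, 0.293 and 0.338 for these. Immediate early genes were 4 higher (3 still called under TMM), with Ier2 at 2.88 ± 0.09 and Egr3 at 1.81 ± 0.09, and 6 lower, with Fosl2 at -1.78 ± 0.07. The mean change of that list was -0.15 and its median -1.30. Camera called it lower than the other tested genes (Benjamini-Hochberg adjusted p = 0.0153). Camera's adjusted p was 0.261 with an estimated correlation and 0.325 with TMM factors. Markers of other cell types were few: Cebpa (adipocyte, 1.20 ± 0.10) was higher, Sox9 (chondrocyte, -2.12 ± 0.11) and Acta1 (muscle, -2.59 ± 0.14) were lower, and 0 of 14 endothelial markers were listed. Of the remaining largest falls, Sik1, a salt-inducible kinase, changed by -3.27 ± 0.09.

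**Figure D3:**
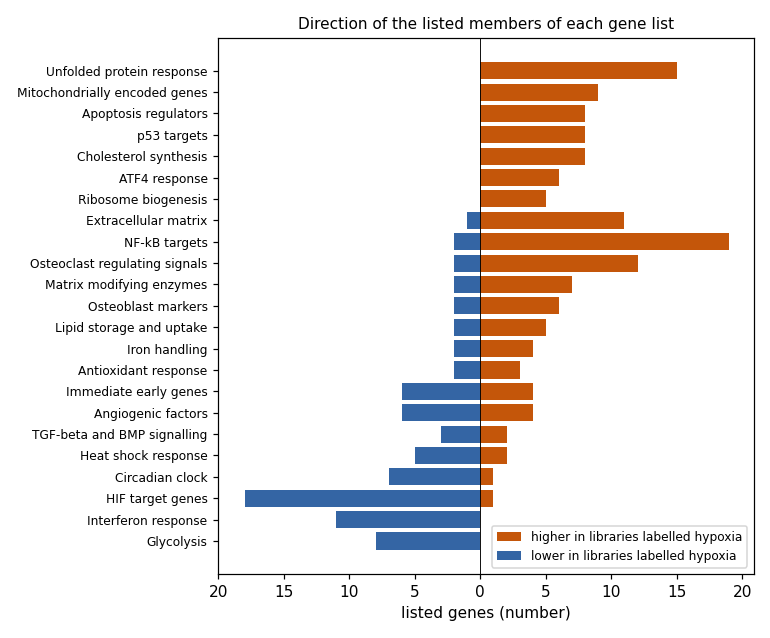
Number of listed members of each gene list with 5 or more that are higher (right of 0) or lower (left of 0) in the libraries labelled hypoxia, on the log2(value + 1) scale as deposited. The 19 NF-kB targets are the longest bar to the right and the 18 HIF targets the longest to the left; in 15 of the 23 lists at least 1 member changes sign under TMM scaling, and in 0 under quantile normalization.

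Camera called 7 of the 23 lists at the preset correlation, all lower as deposited than the other tested genes, and 0 with the estimated one (smallest Benjamini-Hochberg adjusted p = 0.261). The lists share members, such as HIF targets in the glycolysis, clock and angiogenic lists, so their calls are not independent. With quantile normalization or TMM factors camera called 9, among them lists that were higher. In each of the 35 lists with a listed member, every tested member passed limma's threshold, both over all genes tested and adjusted over the list alone, as the genes had been selected for change in these libraries.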

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

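Of 1796 values of the 120 named genes under alternatives, 1763 kept their direction and their side of the threshold. All 2056 tested genes differed by 1 or more on the log2 scale as deposited, 990 with a pseudocount of 5, 634 with quantile normalization and 487 with TMM factors. Genes higher in the libraries labelled hypoxia numbered 546 with TMM factors against 1633, and genes lower 513 against 423, with 90 called genes reversed. TMM centres a table selected for change on its own middle, so by its construction the genes with rises near 1 move to about 0. With it Tyms (-0.0057), Bop1 (-0.0025), Bcl2l1 (-0.014), Ei24 (-0.0012), Dcn (-0.0446), Suclg1 (-0.0434), Acly (-0.0758), Msmo1 (-0.14), Shmt2 (-0.16), Spp1 (-0.20), Polr1b (-0.0723), Gins3 (-0.0117), Rrp12 (-0.0891), G6pdx (-0.23), Ndufa4 (-0.25) and Ccng1 (-0.25) were below 0. TMM factors also ended the calls of 11 named genes that stayed above 0: Psat1, Csf1, Psph, Hif1a, Idi1, Cyp51, Lamb1, Tsr1, Slc11a2, Btg2 and Ndufa9. Quantile normalization ended those of 2, Polr1b and Rrp12. In every refit (pseudocounts, filters, scalings, trend, block and left-out libraries) 18 HIF targets were lower. Of the gene lists, camera called 7 as deposited, all lower than the other tested genes. It called 8 with a pseudocount of 5 or without any 1 hypoxia replicate, 5 at a threshold of 0.01 and 0 with an estimated correlation. With quantile normalization it called 9, and with TMM factors 9. The lists added by these scalings were higher: the unfolded protein response and NF-kB targets under both, and osteoclast signals and mitochondrially encoded genes under TMM, which ended the calls of the angiogenic and immediate early lists. Fry, which does not compare lists, called 23. Leaving out each library in turn gave 1632 to 1633 higher and 419 to 423 lower genes, and 1633 and 422 without normoxia replicate 2, which stood farthest from its group. Samples that share a replicate number (2 and 4) deviated from their groups with r = 0.08 and -0.07, so the numbers were not taken as pairs. The replicate block rests on the 4 libraries that share numbers and gives the same values with the other 2 left out, so it changes both the model and the libraries used. With it, 1627 genes were higher and 418 lower, and camera called 10 lists, adding as higher the unfolded protein response (adjusted p = 0.0164), osteoclast signals (adjusted p = 0.0368) and NF-kB targets (adjusted p = 0.0116), while the calls of Lcn2 (change 5.49, adjusted p = 0.104) and Cxcl2 (change 4.34, adjusted p = 0.0618) ended with changes near those of the fit to all libraries (5.66 and 4.33). Alternatives planned for counts (other size factors, DESeq2, voom, filters on counts) were not run because the values are not counts. Depth is unknown, so limits for low genes could not be set.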

Other observations

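The tests of a single wrong label and of a difference of scale, the further HIF list, the families of gene symbols and the pseudogene alignment were chosen after the first results were seen. Replication-dependent histone genes, which are made mainly in S phase, were lower in the libraries labelled hypoxia, 18 of 20 listed (two-sided Fisher's exact test against the other listed genes, Benjamini-Hochberg adjusted p = 1.3e-09 over 29 symbol families). H3c15 went from 6.14 ± 0.23 to 3.92 ± 0.08 and H2ac19 from 6.77 ± 0.13 to 5.11 ± 0.15 (log2(value + 1), SD, n = 3), while H2bc21 and H2bc18 were higher, H2bc18 with its call ended under TMM. Several members had low values, such as H2ac22 (2.18 ± 0.04 to 0.37 ± 0.30) and H4c6 (1.30 ± 0.36 to 0.28 ± 0.32). How fully the kit for messenger RNA captured histone transcripts was not assessed, so their levels are uncertain. The 3 listed DNA replication genes were higher as deposited, and under TMM all were below 0 and not called. Of the mitosis list 0 of 30 genes were listed, so the fall of histone genes does not show a change in S phase. Solute carriers were higher in 54 of 55 listed cases, the exception being Slc2a1 (exact test, Benjamini-Hochberg adjusted p = 0.000911), and under TMM 10 of the 54 fell below 0 and 18 were still called higher. All 16 listed genes of the interleukin and interleukin receptor family were higher, 3 of them below 0 and 9 still called under TMM (exact test, adjusted p = 0.401).

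Processed pseudogenes were lower in 102 of 150 listed cases, against 263 of 1757 protein-coding genes. For 124 of them the closest other gene that is coding was itself listed, and all 124 went in the direction of that gene, 94 of them lower. Of these 124, 55 were closest to Gapdh, and 15 to a predicted coding gene that is also the closest match of Gapdh-ps16. Reads of such similar copies cannot be assigned with certainty. The pseudogenes are therefore not independent of these coding genes, and their share of lower cases is not evidence about pseudogenes as a class. Under TMM, 17 of the 47 tested pseudogenes that were higher fell below 0, and 7 were still called higher.

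HIF target genes were lower in the libraries labelled hypoxia. A single wrong label could lower them in 1 library only, but a gap of 1.66 (log2) in their mean lay between all 3 libraries of each group, where no library was more than 0.09 from its group mean, so it is not the cause of the fall in all 3. A difference of scale alone would move all genes one way, but 18 of 19 listed HIF targets were lower where 79.4% of tested genes were higher. The HIF targets' median change lay -3.11 from that of the other listed genes. Selection for an absolute change of at least 1 left out genes near 0 and so widened that gap, and its size is not evidence. An exchange of the labels of both groups remains a candidate explanation. Of 54 further HIF targets listed afterwards, 15 were among the selected genes and 93.3% of these (14 genes) were lower. Without Eno2, whose fall was already known, 13 of 14 were lower, and outside the glycolysis, clock and chromatin enzyme lists 7 of 8. In contrast, Fut11 (1.25) of that list, Pfkfb4 (1.46) of the first and Angptl4, a hypoxia-inducible gene on neither, were higher, which an exchange does not account for. With TMM factors Fut11 and Pfkfb4 were not called higher. TMM by its construction moves rises near 1 to about 0, so these lost calls decide nothing here. A true fall of HIF output after 24 h at 2% O2 predicts the same values and stays open, untested. It does not account for Fut11, Pfkfb4 and Angptl4 either.

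Inflammatory genes (19 of 21 listed NF-kB targets) were higher in the libraries labelled hypoxia. Macrophage-like cells in those cultures could bring such transcripts, but only 2 of 18 macrophage and osteoclast markers were listed, Mmp9 higher and Cd68 lower, too few to decide. Handling that raises immediate early genes may also do so; 40.0% of the 10 listed ones were higher, which neither excludes nor supports it. A response to oxygen itself, in either direction of the labels, stays open and was not tested apart from these.

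More of the selected genes were higher than lower. Transcript length and GC content as the whole reason are argued against by the share of higher genes, which stayed above 50% in each of 5 bins of the genes, at 56.65% or more by length and 68.15% or more by GC content. The share was 56.65% in the bin of shortest transcripts and 83.21% to 88.89% in the other length bins. By GC content it reached 85.71%, so both may still contribute. The lower genes fell from 130629 to 35842 in summed linear value. In a unit with a fixed total of 1000000 that fall would raise all other genes together by 0.149 (log2). The total is not known, and one of 359466 would give a rise of 0.5, so this may still contribute. Both sizes are averages that include the listed higher genes. These rose from 47707 to 127143 in summed linear value, which takes up most of the loss, so genes outside the table would rise by less. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 2056 genes, the highest of the others 0, and 1 split reached the real value. The genes had been selected for change between the real groups, so this outcome was largely fixed and decides nothing about chance. At a log2 change of 2 or more, 102 of the selected genes were higher and 99 lower. The median absolute change was 1.234 for higher and 1.518 for lower genes, so the excess of higher genes lay among the smaller changes. A response of more genes in 1 direction stays open as biology.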
